A study of Mus musculus with 12 samples.

How the data were processed

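RNA from bone marrow derived macrophages of C3H/HeN mice was measured on 12 Affymetrix Mouse Gene ST 1.0 arrays. Per the labels' protocols, cells were left unstimulated or stimulated with 100 ng/ml lipopolysaccharide (LPS, a component of the Gram-negative bacterial outer membrane that is sensed by Toll-like receptor 4) for 45 min or 4.5 h (270 min). The uridine analogue 4-thiouridine was added at 200 µM for the last 35 min of each culture, so that RNA made in that window could be biotinylated and purified on streptavidin beads. This purified fraction is called nascent RNA here, and the RNA before purification total RNA. Per the same protocols, 100 ng of nascent and 200 ng of total RNA entered each amplification. Nascent and total RNA at 3 times make 6 groups, each with 2 arrays from 2 independent experiments.

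The deposited values are intensities on a linear scale, 1 per probe set, made by the authors with RMA and the Affymetrix Expression Console, per the submitters' processing notes. Their versions, the background correction and whether all 12 arrays were normalised together are not given in the sources used here. The design fixed before the data were examined assumed log2 values. The deposited intensities had medians of 82.94 to 105.33 over the 12 arrays and maxima of 14259.5 to 29577.9, so log2 was taken before any test. No detection calls were used. The 95th percentile of the 1015 tested olfactory receptor genes (symbols starting with Olfr) on each array served as a background level, chosen after the data were seen. Where all arrays of the dimmer group lay under it, the bound is the brighter group's mean minus the mean of, per array, the higher of that level and the gene's own value. RMA compresses the fold changes of dim genes, and quantile scaling, which RMA includes, hides a shift shared by all genes of an array. Changes are therefore relative to the other genes of the same arrays, and nascent RNA levels are not amounts per cell.

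Of 35557 probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12147 had no entry in the annotation used here. Gene identifiers of 21698 of the named probe sets were found in the RefSeq gene table (assembly GRCm38.p6, used for names only), which changed 0 symbols. The 19938 symbols with a probe set of their own were tested, and 999 of them had more than 1 probe set, of which the one with the highest mean over all arrays was used. No filter on level was applied. Members of gene families with similar sequences, such as guanylate binding proteins, Ifi200 genes and Zfp-named genes, may share signal between probe sets.

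Tests were run in R 4.3.3 with limma 3.58.1, and tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, with matplotlib 3.10.9 for the figures. For the 6 comparisons between times within nascent or total RNA, a mean per group was fitted to all 12 arrays (residual degrees of freedom 6, prior 7.4), with an intensity trend in the variance prior. For the difference between the nascent and the total RNA response, and for nascent over total RNA in unstimulated cells, the difference between the nascent and total array of each culture was taken, because nascent RNA was purified out of the total RNA of the same culture. These 6 differences were fitted with a mean per time (residual degrees of freedom 3, prior 16.8). P values were adjusted by Benjamini-Hochberg over the 19938 genes, and a gene was called at an adjusted p below 0.05. Values are log2 differences between group means of 2 arrays with limma's standard error (SE).

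Gene lists, 30 in number, were chosen to fit macrophages, LPS and RNA turnover and included markers of other cell types that the marrow culture could hold. Each was tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with a correlation estimated from the arrays. Of 270 list tests, 126 were called at the preset correlation and 15 of these also with an estimated correlation: cytokines and chemokines in all comparisons of stimulated with unstimulated cells and in total RNA from 45 to 270 min, inflammatory effector genes in total RNA at both times, and immediate early genes, NF-kB genes and dual specificity phosphatases in total RNA at 45 min. The median, mean and test of a list differed in sign in 29 tests, of which 0 were called.

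Named genes follow a rule. For each comparison of stimulated with unstimulated cells these are the 10 called genes with the largest rise and the 8 with the largest fall, and for the other comparisons the 6 largest in each direction. They had to have the same sign in both experiments and a mean in the higher group at or above the median of all genes' means (6.64 on the log2 scale). Up to 4 called members of each list with the largest change were added, or, where no member was called, the 2 members with the highest level. Groups, comparisons, lists, this rule and all alternatives but quantile scaling over all 12 arrays were set before the data were examined.

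The experiment number pairs the samples, since the labels give 2 independent experiments. Deviations of same-numbered arrays from their group means were correlated at r = -0.295 to 0.645 (median 0.326) over the 15 pairs of groups, and above 0.1 in 10 of them. The 5 others all involve the unstimulated nascent arrays. Among them, nascent and total arrays of unstimulated cells with the same number were correlated at r = -0.055, so the values do not bear out the pairing of these arrays, on which the response differences and nascent over total RNA rest. Fits with the experiment as a block were run beside every test. Alternatives also included other scalings, a filter on dim genes, averaged probe sets, all probe sets, no intensity trend, array weights, each fraction alone, culture as a random block (consensus correlation 0.07), unpaired arrays for the within-culture tests, and leaving out each array or culture in turn. The 2 arrays per group limit the precision of every value. The p values rest on the spread within groups, pooled over the groups of a fit and moderated toward the spread of other genes. In the within-culture tests this prior (16.8 degrees of freedom) outweighs a gene's own spread (3).

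The scripts were tested on simulated data for 19938 genes. For nascent RNA at 45 min, 2, 37, 50 and 50 of 50 genes changed by 0.5, 1, 2 and 3 on the log2 scale were called, as were 16 of 19738 unchanged genes. For the difference between responses at 45 min the counts were 0, 5, 41 and 44 of 50, with 7 unchanged genes called, so 88% of log2 changes of 3 were recovered. Unadjusted p values below 0.05 were given to 5.07% and 4.99% of unchanged genes. The 1 raised list of 20 genes was called and 0 of 200 unchanged lists were. Genes were simulated independently of each other, so this does not test lists whose members vary together. Interferon-stimulated genes, for example, had an estimated correlation of 0.5064 in the comparisons between times.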

Results

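Nascent and total RNA of bone marrow derived macrophages were profiled in unstimulated cells and after 45 and 270 min of LPS, to separate changes in newly made RNA from changes in the RNA pool. Each of the 6 groups held 2 arrays from 2 independent experiments. The log2 values of the 2 arrays of a group were correlated across genes at r = 0.9806 to 0.9891, and no arrays were identical. The spread of values differed between arrays. Their interquartile range was 2.642 and 3.004 in unstimulated nascent arrays, 2.238 to 2.501 in stimulated nascent arrays and 2.322 to 3.016 in total RNA arrays. A narrower spread makes bright genes appear lower and dim genes higher, and quantile scaling, run as an alternative, removes it. Values below are log2 differences between group means, with the SE from limma and n = 2 per group unless stated. Of 89 values between times that were named for their size, 54 had a dimmer group whose arrays all lay under the 95th percentile of 1015 olfactory receptor genes (6.19 to 6.82 on the log2 scale), a background level chosen after the data were seen. For these genes the difference is that of the measured levels, and the fold against that level is given as a lower bound, as it is for examples of gene lists. Where both groups lay under it no change is given. Comparisons of nascent with total RNA have no such bound, and the genes with a group under the level are named there.

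Nascent RNA after 45 min of LPS was compared with that of unstimulated cells. Tnfsf9, the ligand of the co-stimulatory receptor 4-1BB, rose by 6.87 ± 0.23 (at least 87.6-fold, adjusted p = 1.44e-09), with 7.03 and 6.71 in the 2 experiments. The monocyte chemokine Ccl2 rose by 6.01 ± 0.25, Mir155, the gene of a microRNA, by 5.98 ± 0.35, and Ptgs2, the inducible cyclooxygenase, by 5.81 ± 0.19. Egr1 (5.61 ± 0.24), Cxcl10 (5.6 ± 0.22), Cxcl1 (5.51 ± 0.21), Il1b (5.43 ± 0.23), Gbp5 (5.36 ± 0.22) and Il1a (4.92 ± 0.31) completed the 10 largest rises by measured level. The largest fall was that of Tifab, a TIFA-related gene, by -2.45 ± 0.32 (adjusted p = 0.0003). It was followed by Zfp637 (-2.28 ± 0.30), Dok1 (-2.23 ± 0.49), Timm21 (-2.14 ± 0.36), Fahd1 (-2.12 ± 0.26), Trmt12 (-2.10 ± 0.24), Med18 (-2.09 ± 0.36) and Ranbp6 (-2.06 ± 0.26). Against the background level Ccl2 rose at least 45.5-fold, Mir155 at least 42.6-fold and Gbp5 at least 21.2-fold, and Zfp637, Timm21, Fahd1 and Med18 fell at least 2.56-, 3.13-, 2.79- and 2.69-fold. Dok1 was no longer called without the unstimulated nascent array of experiment 2 (-1.35) or the 45 min nascent array of experiment 2 (-2.04).

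Immediate early genes, transcription factors and regulators that need no new protein for induction, rose as a group in nascent RNA at 45 min: 18 of 24 rose, 0 fell and 6 did not pass (22 rose adjusted over the list alone). The immediate early gene list had adjusted p = 1.17e-24, and adjusted p = 0.0522 with an estimated correlation. Ier2 rose by 4.35 ± 0.52, Maff by 4.21 ± 0.29 and Fos by 4.09 ± 0.28. Of the NF-kB family and its feedback regulators 17 of 20 rose and 0 fell (17 adjusted over the list alone), among them Nfkbiz (4.09 ± 0.19) and Nfkbie (3.52 ± 0.29). The NF-kB list had adjusted p = 2.61e-21, and adjusted p = 0.0522 with an estimated correlation. Cytokines (16 of 25 higher, 18 adjusted over the list alone, adjusted p = 1.2e-21) and chemokines (12 of 22 higher, 15 adjusted over the list alone, adjusted p = 1.63e-17) rose with 0 members lower. Tnf rose by 4.73 ± 0.20 and Cxcl2 by 4.62 ± 0.24, and both lists were called with an estimated correlation too (adjusted p = 0.00396 for each). Of the inflammatory effector genes 10 of 18 rose (11 adjusted over the list alone), including Acod1, the itaconate-producing enzyme (4.54 ± 0.25), and the acute phase gene Saa3 (3.43 ± 0.45). The effector list had adjusted p = 3.07e-12, and adjusted p = 0.0555 with an estimated correlation. Of the dual specificity phosphatases, which inactivate MAP kinases, 6 of 13 rose and 0 fell (7 adjusted over the list alone), led by Dusp2 (3.79 ± 0.32). The phosphatase list had adjusted p = 4.43e-05, and adjusted p = 0.0752 with an estimated correlation.

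Of the interferon-stimulated genes 7 of 29 rose in nascent RNA at this time with 0 lower (8 higher and 1 lower adjusted over the list alone). The interferon-stimulated list had adjusted p = 0.0273, and adjusted p = 0.769 with an estimated correlation. These were led by Gbp5, Gbp3 (3.43 ± 0.24) and the transcription factor Irf1 (2.38 ± 0.31), while with the experiment as a block 1 member was lower. Antigen presentation and co-stimulation genes rose in 9 of 21 cases (11 higher and 3 lower adjusted over the list alone), with Cd40 at 3.57 ± 0.22 and Icam1 at 3.36 ± 0.26. The antigen presentation list had adjusted p = 5.8e-05, and adjusted p = 0.417 with an estimated correlation. In this list 0 members fell, against 2 with the experiment as a block. Nuclear genes of oxidative phosphorylation fell: 12 of 32 were lower and 0 higher (20 lower adjusted over the list alone), such as Ndufs3 (-1.63 ± 0.20) and Ndufb8 (-1.54 ± 0.31, at least 2.75-fold lower). The oxidative phosphorylation list had adjusted p = 7.89e-13, and adjusted p = 0.166 with an estimated correlation. Of the Zfp-named zinc finger genes 88 of 317 fell and 9 rose (121 and 10 adjusted over the list alone). The Zfp-named list had adjusted p = 7.36e-16, and adjusted p = 0.0522 with an estimated correlation. The 9 included Zfp36, which encodes tristetraprolin, an mRNA decay factor (2.69 ± 0.28). Among LXR target genes, involved in cholesterol export and lipid synthesis, 1 of 13 fell, Scd2 (-1.72 ± 0.29), against 5 adjusted over the list alone and 5 with the experiment as a block (adjusted p = 0.000572, adjusted p = 0.417 with an estimated correlation).

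Over all 19938 genes, limma called 609 higher and 1172 lower in nascent RNA at 45 min, 403 and 625 of them by at least 2-fold. With quantile scaling within each fraction 415 were higher and 427 lower by at least 2-fold. The median change of all genes was 0.11, and -0.095 with dim genes left out. With the experiment as a block 1838 genes were lower. Without the unstimulated nascent array of experiment 2 the counts were 393 higher and 256 lower, without the 45 min array of experiment 2 they were 343 and 284, and without that of experiment 1 there were 453 lower.

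At 270 min nascent RNA of Il6, a cytokine of the acute phase response, rose by at least 6.67 (at least 102-fold, adjusted p = 2.44e-10), to 12.98 on the log2 scale from a level not shown to be above background (4.2). Edn1, which encodes endothelin (7.75 ± 0.24), the interferon-inducible GTPases Gbp5 (7.18 ± 0.22), Gbp4 (6.88 ± 0.21) and Iigp1 (6.59 ± 0.31), Mir155 (7.17 ± 0.35), Cxcl10 (7.02 ± 0.22), the early activation antigen Cd69 (6.88 ± 0.34), Il1a (6.67 ± 0.31) and AW112010 (6.67 ± 0.32) also rose. The iron exporter Slc40a1 fell by -5.01 ± 0.33 (at least 13.4-fold lower, adjusted p = 1.41e-07). The receptors Cd28 (-5.0 ± 0.20), Cxcr4 (-4.62 ± 0.19) and Cd300lb (-4.58 ± 0.33), the ion exchanger Slc9a9 (-4.78 ± 0.27), Mtss1 (-4.68 ± 0.23), the gamma-secretase subunit Aph1c (-4.63 ± 0.19) and Snx30 (-4.58 ± 0.24) fell too. Against the background level the rises of Edn1, Gbp5, Gbp4, Iigp1, Mir155, Cd69 and AW112010 were at least 135-, 75.4-, 77.8-, 49.2-, 97.7-, 66.1- and 74-fold, and the falls of Cd28, Slc9a9, Mtss1 and Snx30 at least 17-, 14.6-, 20.2- and 13.5-fold.

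Interferon-stimulated genes rose in 28 of 29 cases in nascent RNA at 270 min (29 adjusted over the list alone), for example Mx1, an antiviral GTPase (5.72 ± 0.23), and Gbp3 (5.84 ± 0.24). The interferon-stimulated list had adjusted p = 7.57e-30, and adjusted p = 0.11 with an estimated correlation. Of the chemokines 20 of 22 rose and 1 fell (20 and 1 adjusted over the list alone; adjusted p = 2.72e-15), with Cxcl3 at 5.69 ± 0.22 (at least 40.9-fold) and Ccl5 at 5.48 ± 0.35. Of the cytokines 18 of 25 rose and 1 fell (19 and 1 adjusted over the list alone; adjusted p = 6.09e-19), and both lists had adjusted p = 0.00576 with an estimated correlation. Inflammatory effector genes rose in 16 of 18 cases with 0 lower, against 1 lower with the experiment as a block (16 and 1 adjusted over the list alone), including the inducible nitric oxide synthase Nos2 (5.03 ± 0.21, at least 28.6-fold). The effector list had adjusted p = 5.05e-15, and adjusted p = 0.0655 with an estimated correlation. The NF-kB list had 14 of 20 higher (16 adjusted over the list alone), with Traf1 at 4.25 ± 0.27. The NF-kB list had adjusted p = 3.72e-10, and adjusted p = 0.169 with an estimated correlation. Of the Toll-like receptor signalling genes 13 of 28 rose and 1 fell (13 and 1 adjusted over the list alone), with Tlr3 at 3.30 ± 0.22 and Tlr1 at 3.12 ± 0.29. The Toll-like receptor list had adjusted p = 0.00121, and adjusted p = 0.269 with an estimated correlation. Immediate early genes were not called as a list in nascent RNA at 270 min (4 of 24 higher and 2 lower, 5 and 2 adjusted over the list alone, 7 and 3 with the experiment as a block; adjusted p = 0.404), and Jun, a subunit of AP-1, fell by -3.49 ± 0.38.

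Of the macrophage genes 13 of 24 fell in nascent RNA at 270 min and 3 rose (15 and 4 adjusted over the list alone): the mannose receptor Mrc1 fell by -3.95 ± 0.23, the myeloid transcription factor Cebpa by -3.14 ± 0.38 and the scavenger receptor Cd36 by -3.10 ± 0.53. The macrophage list had adjusted p = 0.000158, and adjusted p = 0.169 with an estimated correlation. LXR target genes fell in 7 of 13 cases with 0 higher (8 adjusted over the list alone), including Abca1, a cholesterol exporter (-2.06 ± 0.24), and Pltp (-2.19 ± 0.32). The LXR list had adjusted p = 1.47e-05, and adjusted p = 0.265 with an estimated correlation. Of the p53 target genes 7 of 17 fell and 1 rose (8 and 1 adjusted over the list alone): Sesn1 fell by -3.44 ± 0.29 and the death receptor Fas rose by 2.23 ± 0.24. The p53 list had adjusted p = 0.0161, and adjusted p = 0.16 with an estimated correlation. In all, limma called 1768 genes higher and 2827 lower, 899 and 1636 by at least 2-fold. The median change was 0.12 over all genes, and -0.22 with dim genes left out. Without the unstimulated nascent array of experiment 2 the counts were 1156 and 1786, without the 270 min array of experiment 2 they were 1074 and 1806, and without that of experiment 1 there were 1875 lower.

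Total RNA at 45 min was compared with that of unstimulated cells in the same way. Tnfsf9 rose by 5.66 ± 0.23 (at least 29.1-fold, adjusted p = 8.01e-09), and the neutrophil chemokines Cxcl2 (5.62 ± 0.24) and Cxcl1 (5.09 ± 0.21), Ptgs2 (5.32 ± 0.19), Tnf (5.27 ± 0.20), Il1b (4.80 ± 0.23), Egr1 (4.72 ± 0.24), Mir155 (4.71 ± 0.35), Nfkbiz (4.62 ± 0.19) and the small GTPase Gem (4.02 ± 0.22) followed. Ptgs2 rose at least 26.4-fold and Mir155 at least 16.7-fold against the background level. Immediate early genes rose in 13 of 24 cases (18 adjusted over the list alone; adjusted p = 1.77e-68) and NF-kB genes in 10 of 20 (15 adjusted over the list alone; adjusted p = 7.68e-57), both with adjusted p = 0.00516 with an estimated correlation. Dusp1 rose by 3.63 ± 0.34, and the NF-kB inhibitors Tnfaip3 by 3.70 ± 0.19 and Nfkbia by 3.39 ± 0.30. Cytokines rose in 8 of 25 cases (13 adjusted over the list alone; adjusted p = 1.18e-42), chemokines in 7 of 22 (9 adjusted over the list alone; adjusted p = 3.04e-30) and inflammatory effector genes in 7 of 18 (8 adjusted over the list alone; adjusted p = 3.74e-25). Dual specificity phosphatases rose in 3 of 13 cases (6 adjusted over the list alone; adjusted p = 3.29e-12). In each of these lists 0 members fell. Limma called 132 genes higher, 128 of them by at least 2-fold, and 81 without the 45 min total RNA array of experiment 2.

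Only 4 genes were called lower in total RNA at 45 min. The rule names 2610005L07Rik (-1.11 ± 0.21, adjusted p = 0.0194), which was not called without the unstimulated array of experiment 1 (-1.11) or 2 (-1.12) or the 45 min array of experiment 1 (-0.85), and Mir340, and Haspin and Mir103-2 were added after their values were seen. Mir340 (5.88 at 0 min and 3.72 at 45 min) and Haspin (5.87 and 5.0) lay under the background level at both times, and Mir103-2 (-1.07 ± 0.22) was at least 1.19-fold lower. With the experiment as a block 17 genes were lower. Without the unstimulated total RNA array of experiment 1 there was 1, and without that of experiment 2 or the 45 min array of experiment 1 limma called 0, with 156 and 191 lower at an unadjusted p under 0.05. Lists that passed at 45 min in total RNA with the experiment as a block and not without it were sterol biosynthesis (adjusted p = 0.0431 against 0.0612), the unfolded protein response (0.0476 against 0.0612) and microRNA entries (0.0476 against 0.0612).

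By 270 min total RNA of Il6 had risen by at least 6.41 (at least 85-fold, adjusted p = 5.79e-10), to 12.69 from a level not shown to be above background (3.97). Il1a (7.51 ± 0.31), Ptgs2 (7.40 ± 0.19), Cxcl10 (6.95 ± 0.22), Ifi205 (6.76 ± 0.30), Cd69 (6.71 ± 0.34), Il1b (6.70 ± 0.23), Edn1 (6.54 ± 0.24), Gbp5 (6.52 ± 0.22) and the interleukin-12 subunit Il12b (6.33 ± 0.24) also rose. Slc40a1 fell by -4.39 ± 0.33 (at least 11.7-fold lower), Cd300lb by -4.25 ± 0.33, the small GTPase Rab7b by -4.07 ± 0.34, Cxcr4 by -4.06 ± 0.19 and the cannabinoid receptor Cnr2 by -3.75 ± 0.30. Tcp11l2 (-3.69 ± 0.19), Rassf3 (-3.64 ± 0.25) and Lhfpl2 (-3.64 ± 0.25) fell as well. Against the background level the rises of Il1a, Ptgs2, Ifi205, Cd69, Edn1, Gbp5 and Il12b were at least 114-, 112-, 60-, 54.3-, 63.9-, 65.3- and 59.3-fold, and the falls of Cd300lb, Cnr2, Tcp11l2 and Rassf3 at least 16.8-, 4.72-, 5.33- and 10.2-fold. All 29 interferon-stimulated genes rose (29 adjusted over the list alone), with Rsad2, an antiviral enzyme, at 5.68 ± 0.36. The interferon-stimulated list had adjusted p = 1.11e-35, and adjusted p = 0.0749 with an estimated correlation. NF-kB genes rose in 18 of 20 cases (19 adjusted over the list alone). The NF-kB list had adjusted p = 2.94e-17, and adjusted p = 0.0828 with an estimated correlation. Cytokines rose in 19 of 25 cases with 1 lower (20 and 1 adjusted over the list alone; adjusted p = 1.46e-25) and inflammatory effector genes in 16 of 18 (16 adjusted over the list alone; adjusted p = 6.2e-21). Chemokines rose in 19 of 22 cases with 0 lower, against 1 with the experiment as a block (19 and 1 adjusted over the list alone; adjusted p = 6.4e-22).

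Antigen presentation and co-stimulation genes rose in 13 of 21 cases in total RNA at 270 min with 0 lower, against 1 with the experiment as a block (14 adjusted over the list alone), led by Cd40 (5.83 ± 0.22) and Icam1 (3.70 ± 0.26). The antigen presentation list had adjusted p = 1.04e-08, and adjusted p = 0.192 with an estimated correlation. Macrophage genes fell in 7 of 24 cases and 1 rose, against 2 with the experiment as a block (7 and 1 adjusted over the list alone): the chemokine receptor Ccr2 fell by -2.48 ± 0.20 and the scavenger receptor Msr1 rose by 1.33 ± 0.21. The macrophage list had adjusted p = 0.0117, and adjusted p = 0.346 with an estimated correlation. LXR target genes fell in 5 of 13 cases (6 adjusted over the list alone), with Scd2 at -2.36 ± 0.29 (at least 4.45-fold lower). The LXR list had adjusted p = 0.000746, and adjusted p = 0.357 with an estimated correlation. Immediate early genes rose in 7 of 24 cases and 1 fell, against 10 and 2 with the experiment as a block (8 and 1 adjusted over the list alone; adjusted p = 0.0272, adjusted p = 0.771 with an estimated correlation). The oxidative phosphorylation list had adjusted p = 0.0514, and 0.044 with the experiment as a block, with 1 of 32 members lower against 4. Limma called 1400 genes higher and 2387 lower, 845 and 1281 by at least 2-fold. Without the unstimulated array of experiment 1 there were 1565 lower, and without the 270 min array of experiment 2 there were 1507.

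**Figure D1:**
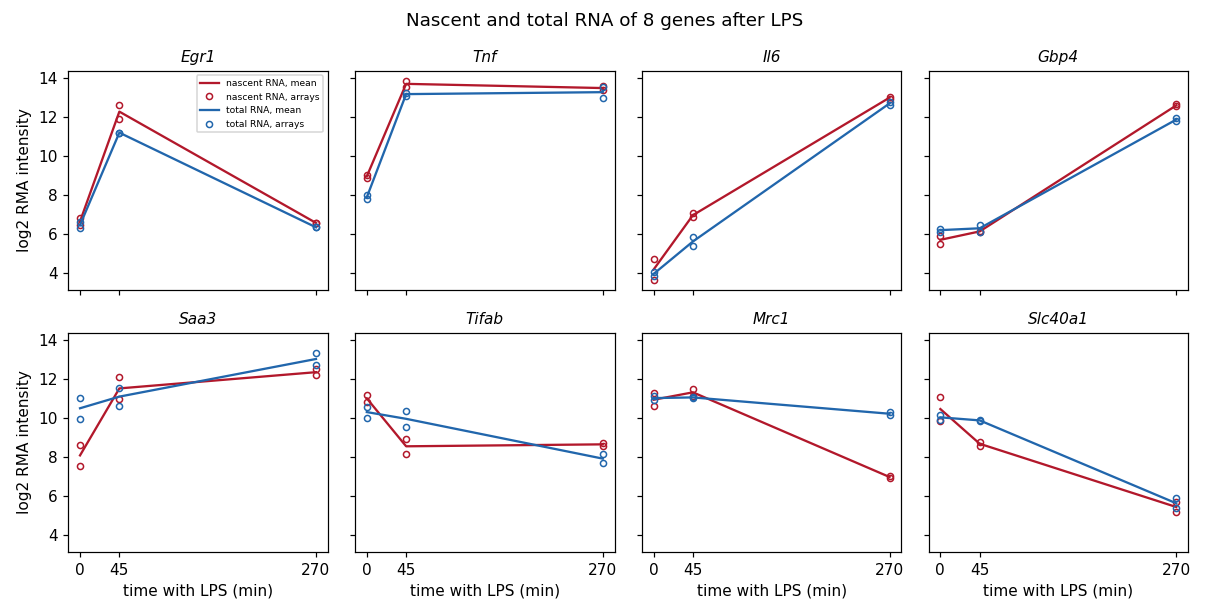
Log2 RMA intensity (vertical axis) of 8 genes against minutes with LPS (horizontal axis), in nascent RNA (red) and total RNA (blue). Open circles are the 2 arrays of each group and lines join their means, with Egr1 high at 45 min alone, Il6 and Gbp4 highest at 270 min, and Mrc1 falling by -3.95 in nascent RNA at 270 min.

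From 45 to 270 min, immediate early genes fell and interferon-stimulated genes rose in both kinds of RNA. Nascent Egr1 fell by -5.69 ± 0.24 (adjusted p = 3.76e-09) and total Egr1 by -4.84 ± 0.24, and of the immediate early genes 18 of 24 fell in nascent RNA with 0 higher (18 lower and 1 higher adjusted over the list alone). The immediate early gene list had adjusted p = 7.38e-17, and adjusted p = 0.132 with an estimated correlation. In total RNA 14 of 24 fell with 0 higher, against 1 higher with the experiment as a block (16 lower and 2 higher adjusted over the list alone). The immediate early gene list had adjusted p = 5.06e-09, and adjusted p = 0.256 with an estimated correlation. Nascent Cd28 (-4.92 ± 0.20), the deiodinase Dio2 (-4.74 ± 0.26), Arhgap18 (-4.62 ± 0.27), Slc9a9 (-4.54 ± 0.27) and Mtss1 (-4.40 ± 0.23) also fell. Interferon-stimulated genes rose in 27 of 29 cases in nascent RNA (28 adjusted over the list alone) and in 28 in total RNA (28 adjusted over the list alone). The interferon-stimulated list had adjusted p = 2.31e-35, and adjusted p = 0.118 with an estimated correlation. The interferon-stimulated list had adjusted p = 4.19e-32, and adjusted p = 0.0755 with an estimated correlation. Nascent Ifi214 rose by 6.72 ± 0.28, Iigp1 by 6.48 ± 0.31, Gbp4 by 6.45 ± 0.21, Edn1 by 6.37 ± 0.24, Mx1 by 6.26 ± 0.23 and AW112010 by 6.08 ± 0.32. Against the background level these rises were at least 20.8-fold for Ifi214, 39.5-fold for Iigp1, 62.5-fold for Gbp4, 59.3-fold for Mx1 and 59.4-fold for AW112010. The nascent falls of Egr1, Cd28, Dio2, Arhgap18, Slc9a9 and Mtss1 were at least 46.5-, 16.1-, 22.4-, 10.4-, 12.4- and 16.7-fold.

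Dual specificity phosphatases fell from 45 to 270 min in 9 of 13 cases in nascent RNA with 1 higher (9 and 1 adjusted over the list alone), including Dusp1 (-3.07 ± 0.34). The phosphatase list had adjusted p = 1.11e-05, and adjusted p = 0.118 with an estimated correlation. Total RNA of Il6 rose by at least 6.5 (at least 90.7-fold) from 45 to 270 min, as did Edn1 (6.14 ± 0.24), Iigp1 (6.0 ± 0.31), Nos2 (5.73 ± 0.21), Mx1 (5.73 ± 0.23) and Il12b (5.61 ± 0.24), while Slc40a1 (-4.24 ± 0.33), Cd300lb (-4.01 ± 0.33), Cxcr4 (-3.90 ± 0.19), Tcp11l2 (-3.86 ± 0.19) and Rab7b (-3.85 ± 0.34) fell. Against the background level Iigp1 and Nos2 rose at least 36- and 45.8-fold, and Slc40a1, Cd300lb and Tcp11l2 fell at least 10.5-, 14.2- and 5.99-fold. Limma called 1344 genes higher and 2001 lower in nascent RNA, and 1324 and 2302 in total RNA. Without the nascent 45 min array of experiment 1 the nascent counts were 882 and 1255, and without the nascent 270 min array of experiment 2 there were 860 higher. Without the total 45 min array of experiment 1 there were 881 higher in total RNA, and without the total 270 min array of experiment 2 there were 1400 lower. The small nucleolar RNA list had adjusted p = 0.0685 in total RNA, and 0.0239 with the experiment as a block.

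Of the genes higher in total RNA at 45 min, 131 of 132 were also higher in nascent RNA, where lists drawn independently would share 4. At 270 min the lists shared 1083 genes higher (124.1 for independent lists) and 1903 lower (338.5), and 0 genes moved in opposite directions. Between 45 and 270 min nascent RNA shared 325 genes higher (54 for independent lists) and 629 lower (166.2), with 39 higher first and lower later and 22 the other way. In total RNA 95 genes were higher at both times (9.3 for independent lists). In 100 simulations of unchanged groups these overlaps reached at most 1 gene. No gene was changed there, so few could be called. The simulations cannot show how much overlap shared arrays add where many genes are called. For the overlaps between 45 and 270 min, part of the excess may come from the shared unstimulated arrays, since each group had 2. The overlaps between nascent and total RNA share no array, but both kinds of RNA came from the same cultures. Across genes, which are not independent replicates, the 45 and 270 min changes were correlated at r = 0.51 in nascent and 0.37 in total RNA, against 0.50 in the simulations, with covariances of 0.224 and 0.075 against 0.025. In nascent RNA 163 genes were higher at 45 min, fell from 45 to 270 min and were not called at 270 min. A further 1421 were called higher at 270 min and not called at 45 min. They were not required to pass the comparison of 270 with 45 min, which called 1344 genes higher in nascent RNA.

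**Figure D2:**
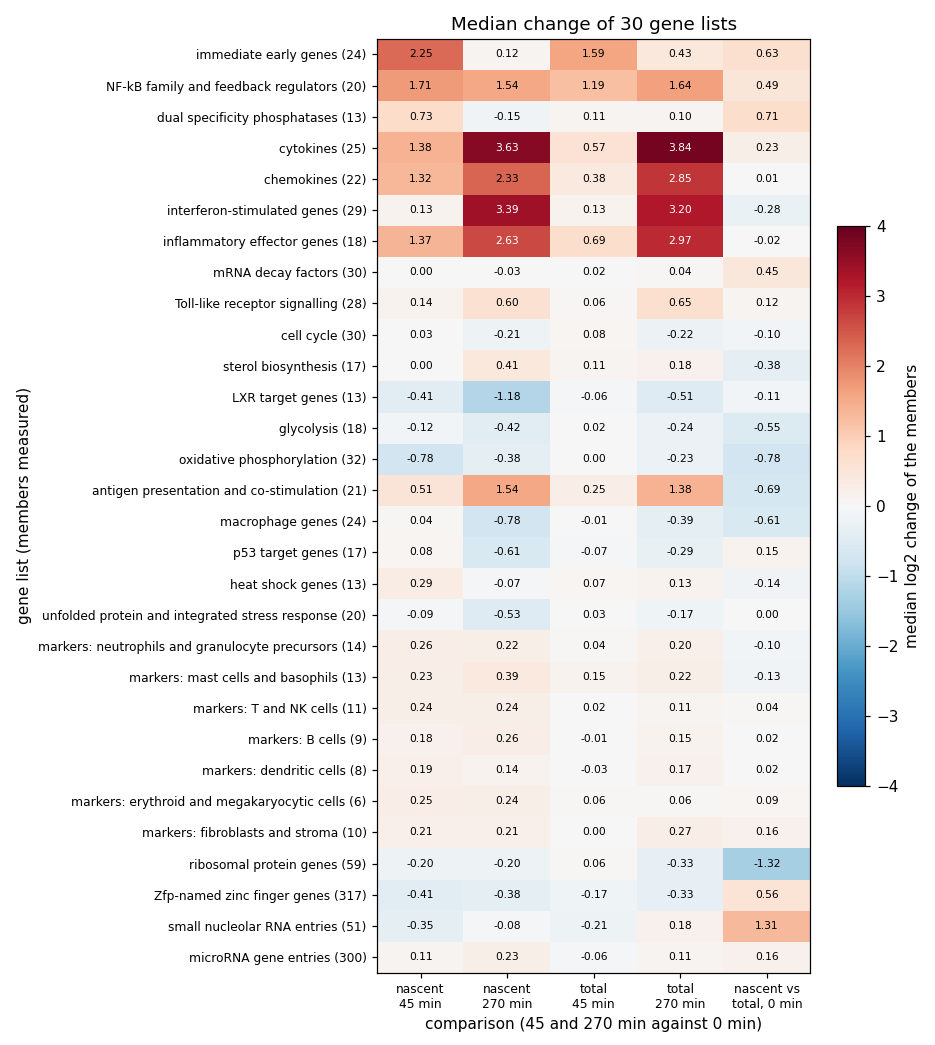
Median log2 change (colour and printed value) of the members of 30 gene lists, 1 per line with the number measured, for nascent and total RNA at 45 and 270 min against 0 min and for nascent against total RNA at 0 min. Interferon-stimulated genes go from a median of 0.13 at 45 min to 3.39 at 270 min in nascent RNA, and ribosomal protein genes have -1.32 in nascent against total RNA.

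Whether nascent RNA responded more than total RNA was tested on the within-culture differences, although the same-numbered nascent and total arrays of unstimulated cells did not deviate together (r = -0.055). At 45 min the response of Saa3 was larger in nascent RNA by 2.83 ± 0.30 (adjusted p = 5.68e-05), as it was for the Mediator subunit Med21 (2.63 ± 0.26), Gbp2b (2.5 ± 0.26), the granule proteoglycan Srgn (2.47 ± 0.32), the fatty acid binding protein Fabp3 (2.42 ± 0.32) and Ccl2 (2.30 ± 0.28). It was more negative for Tifab (-2.10 ± 0.30), Zfp637 (-2.09 ± 0.31), Timm21 (-2.06 ± 0.36), the mitochondrial hydratase Echs1 (-1.91 ± 0.37), the lysosomal enzyme Aga (-1.90 ± 0.30) and Cops6 (-1.81 ± 0.40). Chemokines had 6 of 22 members with the larger nascent response and 0 with the smaller, against 1 with the experiment as a block (9 and 1 adjusted over the list alone). The chemokine list had adjusted p = 8.95e-09, and adjusted p = 0.205 with an estimated correlation. Cytokines had 5 of 25 such members, and 10 with the experiment as a block (13 adjusted over the list alone), including Csf2 (1.82 ± 0.29) and Ifnb1 (1.63 ± 0.27). The cytokine list had adjusted p = 7.36e-10, and adjusted p = 0.26 with an estimated correlation. Oxidative phosphorylation genes were lower in nascent relative to total RNA in 2 of 32 cases, and in 14 with the experiment as a block (17 adjusted over the list alone), with Ndufb8 at -1.61 ± 0.32. The oxidative phosphorylation list had adjusted p = 2.14e-15, and adjusted p = 0.205 with an estimated correlation. Ccl2, Csf2 and Ifnb1 lay under the background level in both kinds of RNA of unstimulated cells, and Zfp637, Timm21, Cops6 and Ndufb8 in nascent RNA at 45 min. Ifnb1 also lay under it in total RNA at 45 min, so its total RNA response was not measured. The microRNA list had adjusted p = 0.0622, and 0.0461 with the experiment as a block.

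Limma called 87 genes with a higher and 86 with a lower nascent than total response at 45 min, and 257 and 811 with the experiment as a block. With unpaired arrays limma called 3 higher and 0 lower (1147 lower at an unadjusted p under 0.05). The share of called genes that were higher was 50.3%, but 89.6% with quantile scaling within each fraction (69 higher and 8 lower) and 88.9% with quantile scaling over all arrays (72 and 9). Without the 45 min culture of experiment 1 limma called 0 and 0 (1500 higher and 1119 lower at an unadjusted p under 0.05), and without that of experiment 2, 12 and 0 (813 lower at an unadjusted p under 0.05). Without the unstimulated culture of experiment 1 the counts were 294 and 1185, and without that of experiment 2 there were 144 higher. All 12 genes named here lost their call without the 45 min culture of experiment 1, where Saa3 had 2.73 and Tifab -2.07.

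At 270 min the nascent response exceeded the total response for Cd72, a C-type lectin of B cells and macrophages, by 2.24 ± 0.37 (adjusted p = 0.00464), AW112010 (2.07 ± 0.36), Ms4a4c (2.06 ± 0.34), Ccl5 (1.98 ± 0.32), Ly6e (1.73 ± 0.38) and Saa3 (1.73 ± 0.30). It was more negative for Slc9a9 (-3.21 ± 0.32, adjusted p = 3.57e-05), Mrc1 (-3.15 ± 0.32), the transferrin receptor Tfrc (-2.5 ± 0.31), Pmp22 (-2.46 ± 0.36), the protease Ctsk (-2.42 ± 0.32) and Cd36 (-2.40 ± 0.30). Macrophage genes had 3 of 24 members with the more negative nascent response and 0 with the more positive, against 2 with the experiment as a block (4 and 3 adjusted over the list alone). The macrophage list had adjusted p = 0.00229, and adjusted p = 0.87 with an estimated correlation. Chemokines had 3 of 22 more negative, 7 with the experiment as a block, and 1 more positive (10 and 2 adjusted over the list alone). The chemokine list had adjusted p = 9.57e-05, and adjusted p = 0.567 with an estimated correlation. Cytokines had 2 of 25 more negative and 0 more positive, against 3 and 2 with the experiment as a block (4 and 1 adjusted over the list alone; adjusted p = 0.0392, adjusted p = 0.0553 with the experiment as a block and adjusted p = 0.87 with an estimated correlation), with Il23a at -2.10 ± 0.27. Il23a in both kinds of RNA and AW112010 in nascent RNA lay under the background level in unstimulated cells, as Slc9a9 did in nascent RNA at 270 min.

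Limma called 15 genes with a higher and 116 with a lower nascent than total response at 270 min, 105 and 301 with the experiment as a block, and 2 and 47 with unpaired arrays. With quantile scaling within each fraction the counts were 6 and 54, and over all arrays 8 and 59. Without the unstimulated culture of experiment 1 the counts were 188 and 643, without that of experiment 2 there were 38 higher, and without the 270 min culture of experiment 1 they were 8 and 59. With all probe sets tested limma called 0 at both times (783 higher and 915 lower at an unadjusted p under 0.05 at 270 min, 1013 and 1767 at 45 min). All 12 genes named here lost their call there. Without the 270 min culture of experiment 2, Cd72 (2.03), Saa3 (1.57) and Ly6e (1.66) were not called, and Ly6e (1.81) was not called without that of experiment 1.

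**Figure D3:**
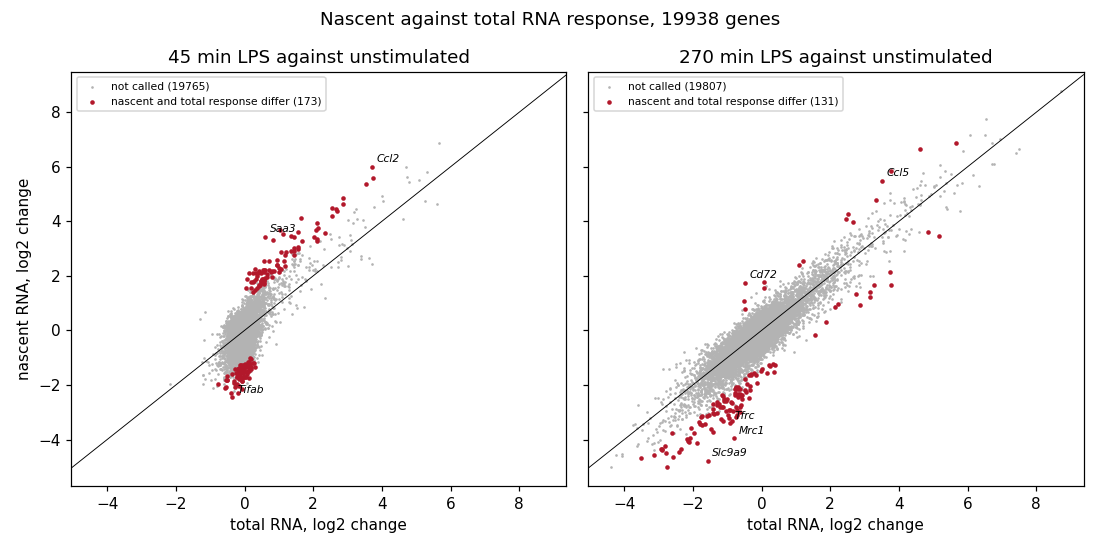
Log2 change in nascent RNA (vertical axis) against total RNA (horizontal axis) for 19938 genes at 45 min (left) and 270 min (right) of LPS, with the line of equal change. Red points are genes whose nascent and total responses differed by the within-culture limma test (173 at 45 min and 131 at 270 min), with Slc9a9 and Mrc1 below the line at 270 min.

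Nascent and total RNA of unstimulated cells were compared within each culture. The small nucleolar RNA entries Snord87 (2.83 ± 0.67, adjusted p = 0.00556), Snord37 (2.51 ± 0.48) and Snord95 (2.18 ± 0.33), 4632427E13Rik (2.46 ± 0.38), Mir677 (2.44 ± 0.44) and Tnfaip3 (2.32 ± 0.27) were highest in nascent over total RNA. Whether probe sets of small nucleolar RNA entries read the small RNA or a longer transcript was not tested. The lowest values were those of Rny3 (-4.54 ± 0.42, adjusted p = 1.14e-05), Vaultrc5 (-3.89 ± 0.46), Rpph1 (-3.48 ± 0.40) and n-R5s136 (-3.21 ± 0.39), followed by the secreted proteins Gpx3 (-2.88 ± 0.31) and Wfdc17 (-2.80 ± 0.27). With all probe sets tested, Rny3 (-4.54), Vaultrc5 (-3.89), Rpph1 (-3.48), n-R5s136 (-3.21) and Snord87 (2.83) were not called. With median centring Snord87 (2.82), Snord37 (2.5), 4632427E13Rik (2.44) and Mir677 (2.43) were not called, and Snord87 (2.77) was not called with quantile scaling within each fraction. Snord37 in total RNA and Vaultrc5 in nascent RNA lay under the background level. Of the ribosomal protein genes 47 of 59 were lower in nascent RNA and 2 higher (50 and 2 adjusted over the list alone), with Rps9 at -2.44 ± 0.32. The ribosomal protein list had adjusted p = 6.88e-30, and adjusted p = 0.204 with an estimated correlation. Oxidative phosphorylation genes were lower in 20 of 32 cases with 0 higher (25 adjusted over the list alone), for example Cox7b (-1.76 ± 0.28). The oxidative phosphorylation list had adjusted p = 2.93e-14, and adjusted p = 0.204 with an estimated correlation.

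Small nucleolar RNA entries were higher in nascent RNA in 38 of 51 cases with 1 lower, against 2 lower with the experiment as a block (43 and 2 adjusted over the list alone), and Zfp-named genes in 139 of 317 cases with 2 lower, against 5 (177 and 5 adjusted over the list alone). The small nucleolar RNA list had adjusted p = 2.16e-22, and adjusted p = 0.29 with an estimated correlation. The Zfp-named list had adjusted p = 1.41e-22, and adjusted p = 0.204 with an estimated correlation. Immediate early genes were higher in 11 of 24 cases with 1 lower (12 and 1 adjusted over the list alone), among them Klf6 (1.79 ± 0.27) and Btg2 (1.76 ± 0.29). The immediate early gene list had adjusted p = 7.39e-07, and adjusted p = 0.47 with an estimated correlation. Antigen presentation genes were lower in 10 of 21 cases and 1 higher (12 and 1 adjusted over the list alone), with Cd74 at -1.93 ± 0.24. The antigen presentation list had adjusted p = 2.48e-06, and adjusted p = 0.47 with an estimated correlation. Sterol biosynthesis genes had adjusted p = 0.0447, and 0.074 with the experiment as a block (2 of 17 lower, 5 with the block, 4 adjusted over the list alone; adjusted p = 0.665 with an estimated correlation). Limma called 1617 genes higher and 1610 lower in nascent than in total RNA, and 1035 higher without the unstimulated culture of experiment 2.

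Lists of markers covered other cell types that the culture could hold. In nascent RNA at 270 min the list of mast cell and basophil markers had 2 of 13 members higher (2 adjusted over the list alone; adjusted p = 0.115, and 0.0399 with the experiment as a block), Kit (0.82 ± 0.22) and Mcpt2, which lay under the background level in both groups. In total RNA at 270 min fibroblast and stroma markers had 2 of 10 higher (2 adjusted over the list alone; adjusted p = 0.0152, adjusted p = 0.192 with an estimated correlation): the growth factor receptor Pdgfrb rose by 3.39 ± 0.17 (at least 9.42-fold), and the matrix proteoglycan Dcn lay under the background level in both groups. The lists for neutrophils (adjusted p = 0.422), T and NK cells (0.745), B cells (0.817), dendritic cells (0.484) and erythroid and megakaryocytic cells (0.706) did not pass in total RNA at 270 min. Single members were called there: 1 higher (S100a8, 1.09, at least 1.66-fold) and 1 lower for neutrophils, and 1 lower each for T and NK cells and B cells. Cd28, which fell by -5.0 in nascent RNA at 270 min, belongs to the T and NK list. In unstimulated cells 3 of 13 mast cell and basophil markers were lower in nascent than in total RNA (3 adjusted over the list alone; adjusted p = 0.028, adjusted p = 0.522 with an estimated correlation), among them Mcpt8 (-1.98 ± 0.37) and Cpa3 (-1.69 ± 0.30).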

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

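The tests of array scaling, of unlabelled RNA carried over for both 45 min patterns and of proliferation were chosen only after the results were seen. The tests of chance values in the unstimulated nascent arrays and of the Mki67 probe set were chosen before their results were seen.

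Nascent RNA at 45 min had 1172 genes lower and 609 higher, but without the unstimulated nascent array of experiment 2 the counts were 256 and 393, and without the 45 min nascent array of experiment 2 they were 284 and 343, so which side is larger rests on single arrays. With quantile scaling within the nascent arrays 878 genes were called lower and 600 higher, and 795 of the 878 were among the 1172. Scaling as the only source of these calls is argued against by the 795. The test counted lower genes alone, and its limit, which 878 passed, was set after the results were seen. By at least 2-fold 427 genes were lower and 415 higher, against 625 and 403 without this scaling. The excess of genes lower by at least 2-fold thus largely went with the scaling. Chance values of the unstimulated nascent arrays as the only source are argued against by total RNA at 270 min, which uses none of the nascent arrays: the 1172 genes had a median change of -0.50 there, below all of 10000 random lists matched on level (-0.22 to -0.08), although how many of the genes chance accounts for stays open. The random lists drew genes independently of each other, so for genes that vary together their range may be too narrow. More unlabelled RNA in the nascent fraction at 45 min would raise genes of low nascent share relative to others. Oxidative phosphorylation genes, of low share (median -0.87 at 270 min), had a median change of -0.78. Their fall was known when the test was chosen, and 12 of the 32 are themselves among the 1172. Ribosomal protein genes, also low in nascent over total RNA, had -0.20. Neither list rose, but these lists cannot decide the question for the 1172 genes as a set. If carry-over were the only source, the 1172 genes would have a high nascent share. Their median nascent over total RNA at 270 min was -0.03, and 9850 of 10000 random matched lists were as high (range -0.06 to 0.06). This argues against carry-over as the only source for the set. The share was measured after LPS and may differ from that in unstimulated cells, so a part from carry-over stays open. A fall in synthesis as a response to LPS stays open and was not tested.

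The difference between nascent and total RNA responses at 45 min was higher for 87 genes and lower for 86 (Saa3 at 2.83 and Tifab at -2.10), but for 69 and 8 with quantile scaling within each fraction, 257 and 811 with the experiment as a block, 3 and 0 with unpaired arrays (1147 lower at an unadjusted p under 0.05 by limma), 0 and 0 with all probe sets (1013 and 1767 unadjusted), and 0 and 0 without the 45 min culture of experiment 1 (1500 and 1119 unadjusted). At 270 min it was higher for 15 and lower for 116 (Cd72 at 2.24 and Slc9a9 at -3.21), but for 6 and 54, 105 and 301, and 2 and 47 in the first 3 of these settings, and 0 and 0 with all probe sets (783 and 915 at an unadjusted p under 0.05 by limma). For the 87 genes, unlabelled RNA carried over at 45 min would raise genes of low nascent share. The 200 genes with the lowest nascent-over-total value in the unstimulated culture of 1 experiment were measured in the other. Their median nascent change at 45 min was -0.72 (quartiles -1.22 and -0.21) in experiment 2 and -0.10 (-0.39 and 0.24) in experiment 1. No rise was seen, but these values were unscaled. The interquartile range of the nascent arrays fell from 3.004 to 2.238 in experiment 2 and from 2.642 to 2.501 in experiment 1. A narrower spread lowers bright genes and could mask a rise, so this does not exclude carry-over. Chance values of the unstimulated nascent arrays as the only source are argued against by total RNA at 270 min, where the 87 genes had a median change of 1.64, above all of 10000 random matched lists (-0.46 to 0.18). Here too the random lists drew genes independently, and their range may be too narrow for genes that vary together. A response to LPS stays open and was not tested.

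Mki67, a proliferation marker, rose in nascent RNA by 4.49 ± 0.24 at 45 min (at least 19.5-fold) and 3.47 ± 0.24 at 270 min (at least 9.64-fold), and in total RNA by 2.56 ± 0.24 and 2.93 ± 0.24. The 29 other cell cycle genes of the list had a median total RNA change at 45 min of 0.08 (-0.21 to 0.34). Few genes were called in total RNA by then (132 higher and 4 lower), so this says little on proliferation. With Mki67 included the list was called higher there by limma's camera (22 of 30 above 0, adjusted p = 0.0374, adjusted p = 0.551 with an estimated correlation). In nascent RNA at 45 min the list with Mki67 had a median of 0.03, with 1 of 30 higher and 1 lower (adjusted p = 0.534 by camera). At 270 min proliferation as the source is argued against by the same 29 genes, whose median total RNA change was -0.23 (quartiles -0.66 and -0.10). Of these 4 were above 0, among them Ccnd2 at 5.38 ± 0.20. Of all 30 members 3 rose and 8 fell (3 and 11 adjusted over the list alone, adjusted p = 0.0561 by camera). A signal of another transcript on the probe set cannot be told apart from Mki67, because only 1 probe set carries this symbol. A response of Mki67 itself to LPS stays open and was not tested.

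Probe sets outside the comparisons also changed in the limma fit of all probe sets. Of the 12147 with no annotation entry, 104 were higher and 756 lower in nascent RNA at 45 min, and 555 higher and 666 lower at 270 min. In total RNA 4 of them were higher and 40 lower at 45 min, and 276 higher and 421 lower at 270 min. In nascent over total RNA of unstimulated cells 1900 of them were higher and 619 lower. What these probe sets measure, and whether control probe sets are among them, is not given by the annotation used here. Of the 1621 with several symbols, 28 were higher and 64 lower in nascent RNA at 45 min, and 73 higher and 69 lower at 270 min. In total RNA limma called 3 of them higher and 0 lower at 45 min (49 lower at an unadjusted p under 0.05), and 67 higher and 55 lower at 270 min.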

How the results depend on the processing

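Quantile scaling over all 12 arrays was the alternative chosen after the data were seen; all others were planned. Genes named for their size had by rule the largest changes and the same sign in both experiments, so a turn was unlikely. Among them 0 turned direction in any setting. All of those named at 270 min against 0 min, and from 45 to 270 min, kept their call in nascent and in total RNA in each of 15 settings. At 45 min Dok1 lost its call in nascent RNA without an array of experiment 2, and 2610005L07Rik in total RNA in 5 settings. All 24 calls of the response differences and 8 of 12 of nascent over total RNA were lost in at least 1 setting. Except where stated, the cause was not tested.

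With the experiment as a block, 1838 genes were lower in nascent RNA and 17 in total RNA at 45 min. The response differences had 257 higher and 811 lower at 45 min, and 105 and 301 at 270 min. The block changed no other call of a gene list than those given beside the results, and moved no other count of genes over a comparison by more than 1.5 times.

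The response difference at 45 min had 3 higher and 0 lower genes with unpaired arrays (1147 lower at an unadjusted p under 0.05 by limma), 54 and 47 with median centring, and 56 and 24 with array weights. It had 8 lower with quantile scaling within fractions, 9 with quantile scaling over all arrays, 51 without dim genes, 141 without the intensity trend, and 0 and 0 with all probe sets (1013 and 1767 at an unadjusted p under 0.05). At 270 min it had 2 and 47 with unpaired arrays, 6 and 54 with quantile scaling within fractions, 8 and 59 over all arrays, 9 higher with median centring, 8 without dim genes, 23 with array weights, and 0 and 0 with all probe sets (783 and 915 at an unadjusted p under 0.05). With all probe sets, which adds features to the test, total RNA at 45 min had 41 lower, nascent RNA from 45 to 270 min 2393 higher, and nascent over total RNA 2972 higher and 2490 lower. Total RNA at 45 min had 2 lower with quantile scaling over all arrays and 2 without the intensity trend.

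With an estimated correlation the lists called fell from 13 to 2 (nascent RNA at 45 min), 15 to 2 (nascent at 270), 13 to 6 (total at 45), 14 to 3 (total at 270), 14 to 0 and 19 to 2 (nascent and total, 45 to 270), 10 to 0 and 13 to 0 (response differences at 45 and 270), and 15 to 0 (nascent over total). Without dim genes 12 lists were called in total RNA from 45 to 270 min and 8 in the response difference at 270 min, which had 7 with quantile scaling within fractions and 8 over all arrays.

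Leaving out an array or culture in turn leaves a group with 1 sample, assumed to vary like the others. Genes higher and lower then ranged from 343 to 539 and 256 to 1510 (nascent at 45 min), 1074 to 1643 and 1786 to 2904 (nascent at 270), 81 to 118 and 0 to 3 (total at 45; 156 or 191 lower at an unadjusted p under 0.05 where limma called 0), 947 to 1797 and 1507 to 2180 (total at 270), 860 to 905 and 1255 to 1642 (nascent, 45 to 270), and 881 to 1956 and 1400 to 2205 (total, 45 to 270). For the response differences they ranged from 0 to 294 and 0 to 1185 at 45 min, and 8 to 188 and 59 to 643 at 270 min, and for nascent over total RNA from 1035 to 1489 and 1188 to 1749. Lists called ranged from 11 to 15, 14 to 18, 9 to 16, 12 to 17, 12 to 15, 18 to 20, 11 to 15, 5 to 12 and 13 to 14 in the order given in the paragraph above. The 5 lists of the response difference at 270 min came without the unstimulated culture of experiment 2 and, equally, without the 270 min culture of experiment 1. Signal over background limits dim genes, whose folds RMA compresses and for which no detection calls were used.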

Other observations

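MicroRNA gene entries and stress genes were also measured. Mir155 was joined by Mir222 (3.51 ± 0.26) and Mir221 (3.33 ± 0.29) in nascent RNA at 45 min, and all 3 were also higher in total RNA at 45 min, at 4.71 ± 0.35, 3.06 ± 0.26 and 3.09 ± 0.29. Of the 20 genes of the unfolded protein and integrated stress response, 5 fell and 0 rose in nascent RNA at 270 min, against 8 lower with the experiment as a block (7 lower adjusted over the list alone; adjusted p = 0.00273 by limma's camera, adjusted p = 0.269 with an estimated correlation), among them Ddit3 (-1.38 ± 0.23) and Atf6 (-1.22 ± 0.22). Ppp1r15a, a phosphatase subunit of that list, rose in nascent RNA at 45 min (2.52 ± 0.28) and in total RNA at both times (2.73 ± 0.28 and 1.61 ± 0.28).

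Of the factors of mRNA decay 3 of 30 rose and 0 fell in total RNA at 45 min (4 higher adjusted over the list alone; adjusted p = 0.0024, adjusted p = 0.245 with an estimated correlation), and 9 were higher and 1 lower in nascent over total RNA of unstimulated cells (14 and 2 adjusted over the list alone; adjusted p = 1.79e-05, adjusted p = 0.47 with an estimated correlation). In nascent RNA at 270 min 4 of 30 rose and 6 fell (4 and 6 adjusted over the list alone; adjusted p = 0.651): Dcp2, the decapping enzyme, rose by 2.49 ± 0.20 and the zinc finger gene Zc3h12c by 2.46 ± 0.22, while Zfp36l1 fell by -3.67 ± 0.22 (at least 9.25-fold) and Zfp36l2 by -1.73 ± 0.19. Zfp36 itself rose at 45 min in nascent (2.69 ± 0.28) and total RNA (2.80 ± 0.28). The cyclin Ccnd2 rose by 5.40 ± 0.20 in nascent and 5.38 ± 0.20 in total RNA at 270 min, in a cell cycle list with 3 of 30 higher and 7 lower in nascent RNA (3 and 7 adjusted over the list alone; adjusted p = 0.145).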
